A study of Mus musculus with 22 samples.

How the data were processed

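The series holds an mRNA library and a hashtag library for each of 11 10x runs, 22 GEO samples in all, of microglia sorted from mouse brain. The mice carry floxed alleles of Aph1, which encodes a subunit of gamma-secretase, in strains that the labels name C57Bl6 and APP-NLGF (C57 and NLGF in the figures), the latter a knock-in of App that leads to amyloid plaques. Per the labels, tamoxifen at 2 mg/kg per day or corn oil was injected on 5 days at 1 month of age, and brains were taken at 3, 6 or 7 months. Cells were dissociated with a transcription inhibitor present and sorted for CD11b, a medium level of CD45 and viability, about 15000 per mouse, of which about 2000 per mouse were pooled with a hashtag antibody for each mouse. The 6-month set (QC) was made to look at effects of tamoxifen. For Ctrl mice at 3 and 7 months the labels do not say which got corn oil and which got tamoxifen without Cre, so cKO against Ctrl there can hold an effect of tamoxifen as well as of the loss of Aph1. The labels name the arms of the QC set cKO and Ctrl and do not say whether the mice carried a Cre driver. Because Aph1a was not lower there, these animals are called mice labelled cKO.

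The deposited matrices hold UMI counts of genes and of hashtags per barcode, and this unit, count, was checked on each of the 11 matrices: all values are whole numbers, and the lowest total per barcode is 500 or 501. Per the file headers, the authors made them with Cell Ranger 6.0.1, while the submitters' processing notes name Cell Ranger 3.0.2, Seurat 4.1.1 and the genome build mm10. Each matrix has 32285 gene rows at 3 months and 32286 at 6 and 7 months. The row of Clec7a is absent at 3 months, so this gene was not analysed there. Coordinates come from GENCODE release M21 on GRCm38 (mm10), in which 32159 of the 32286 gene names of the matrices (99.61%) were found.

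Cells were assigned to mice within each library with HTODemux of Seurat 5.3.0 (positive quantile 0.99), using the tags in the matrix. Between 2.76% and 7.25% of the barcodes of a library were doublets and between 5.32% and 23.9% were negative, and all of these were left out. Cells that this rule or the margin rule below assigned to a mouse, with at least 500 genes and at most 10% mitochondrial UMIs (68330 cells), were clustered together. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes (by variance over genes of like mean, without mitochondrial, ribosomal and sex-linked genes) gave 30 principal components. A graph of 15 nearest neighbours (scikit-learn 1.9.0) was clustered by Leiden at resolution 0.5 (igraph 0.11.9, leidenalg 0.10.2). Of the 11 clusters, 8 were microglia-like, with a mean level of the microglia markers at least 0.5 times that of all cells and at least 10 of them detected. A cluster was named after a marker list when at least 3 of its genes were 2-fold or more over the other cells. This gave 1 border macrophage-like cluster (2539 cells) and 1 endothelial-like cluster (442 cells). A cluster of 7054 cells with a median of 1267 UMIs also met the level of the microglia markers. It got no name, since its UMIs were 0.284 times those of its libraries, under a limit of 0.333, with no microglia marker among its top 10 genes, and is called the low-depth cluster. Clusters are numbered by size and described by leading genes: Tagln2 and Pde2a in cluster 0, Il7r and Tsix in cluster 2, Spp1, Gpnmb, Cst7 and Itgax in cluster 3, and Hspa1a and Hspa1b in cluster 4. UMIs of microglia-like cells were summed per mouse, and the mouse was the replicate.

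The labels list 41 tags, of which 40 are in the matrices, and 39 mice were used (19 female, 20 male), with 700 to 2688 microglia-like cells and 2515357 to 21928992 UMIs each, 56814 cells in all. One 3-month C57Bl6 cKO mouse (replicate 1), whose hashtag stained few cells, was left out by a minimum of 100 microglia-like cells that was set after the hashtag counts were seen, so this group has 3 mice and the 3-month fit 15 mice in place of 16. For the fifth QC library the labels list 4 tags and the matrix holds 3. For one male Ctrl mouse of this library the labels give no strain, while the name of its tag in the deposited matrix reads NLGF control. Groups were fixed from the labels, so this mouse is called unassigned and went into no main comparison, and it was counted as APP-NLGF Ctrl in an added alternative. Xist was at least 1041 CPM in every female and at most 43.9 CPM in every male, and the sum of Ddx3y, Eif2s3y, Kdm5d and Uty was at most 6.4 CPM in females and at least 145 CPM in males, so sex matched the label in all mice used.

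Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM factors, filterByExpr by group, a robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The 3-month fit had sex as a term (10915 genes, 10 residual degrees of freedom). Each 3-month group had its own library, so library could not be a term, and the 3-month libraries had 2 rounds of sequencing against 1 at 6 and 7 months. The 7-month fit (8 mice, 12484 genes, 4 degrees of freedom) and the QC fit (15 mice, 11820 genes, 6 degrees of freedom) had library and sex. The comparison of strains within the QC set had sex alone, since 1 library held mice of both strains. That library held no APP-NLGF mouse labelled cKO. With library as a term, its APP-NLGF Ctrl mouse (replicate 3) thus adds nothing to the fitted QC comparison of arms in APP-NLGF mice. Differences between effects were tested as contrasts of contrasts, within the same fit or in joint fits of 7 and 6 months (library and sex, 12409 genes) and of 7 and 3 months (sex, 11326 genes). Fold changes are log2 values ± standard error, which was taken from the F statistic, and CPM are mean ± SD over mice with TMM factors. CPM of single mice are without TMM factors. CPM do not remove library differences, so at 6 months they can differ from the fitted fold change.

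Before the data were examined, 21 gene lists were fixed: gamma-secretase subunits, homeostatic microglia, DAM (disease-associated microglia) stage 1 and stage 2, interferon response, MHC class II, MHC class I, lysosome, cholesterol synthesis, lipid efflux and LXR targets, proliferation, cytokines and chemokines, immediate early genes, Notch pathway, gamma-secretase substrates, TGF-beta pathway, TREM2 signalling and Alzheimer risk, complement, glycolysis, oxidative phosphorylation and estrogen receptor. A list of sex-linked genes, a DAM index of 12 genes (11 at 3 months) and marker lists of 14 cell types were fixed with them. Lists with at least 3 tested genes were tested with camera (preset correlation 0.01, log CPM with prior count 2), with camera at an estimated correlation and with fry, adjusted over the lists. fry asks whether a list's genes move one way on balance and does not compare them with other genes. The same step fixed the comparisons, the tests and the rule for named genes: the 7 subunit genes in each comparison of cKO with Ctrl, up to 3 members per list and direction with the largest absolute log2 fold change among those with adjusted p under 0.05, and up to 10 genes per direction with the largest change, adjusted p under 0.05, a mean of at least 20 CPM and no overlap between the mice of the groups. Sex-linked, mitochondrial and predicted genes were left out of the last part. Results of some genes are not reported here, although list tests and counts include them. Genes outside this rule, among them cell type markers and the genes of the differences between effects, were chosen after their values were seen.

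The share of DAM-high cells per mouse is the percentage of microglia-like cells with at least 2 (3 months) or 3 (6 and 7 months) UMIs of the DAM index after thinning each cell to 1500 UMIs. These cutoffs are the 99th percentile of C57Bl6 Ctrl cells of the same set, with the 6-month value used at 7 months. It is a range of a score and not a cell type. Between 10 and 178 cells per group were shallower and left out, and between 5.14% (6-month C57Bl6 Ctrl) and 30.5% (3-month APP-NLGF cKO) of cells lay near the cutoff. Shares were compared with two-sided exact permutation tests, whose smallest p is 0.0571 for 3 against 4 mice and 0.0286 for 4 against 4. At 7 months they were also permuted within library and sex (16 arrangements, smallest p 0.125), and at 6 months, after the data were seen, within library (24 arrangements in C57Bl6 and 9 in APP-NLGF mice, smallest p 0.0833 and 0.111).

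The fits were tested on simulated data with 200 changed genes each. At true changes of 1.25, 1.5, 2 and 4-fold, the share recovered was 32%, 71.4%, 86% and 100% for 3-month C57Bl6 cKO against Ctrl (10800 genes), 26.5%, 60%, 92% and 100% for 3-month APP-NLGF cKO against Ctrl (10786 genes), 44%, 84%, 84% and 98% for APP-NLGF against C57Bl6 Ctrl at 3 months (10798 genes), and 49%, 75%, 88% and 98% at 7 months (12390 genes). It was 26%, 64%, 86% and 95.9% for the QC C57Bl6 mice (11660 genes), 20.4%, 66%, 96% and 98% for the QC APP-NLGF mice (11647 genes) and 0%, 8.16%, 52% and 96% for APP-NLGF against C57Bl6 in the QC set (11688 genes). False calls made up a mean of 5.39%, 5.25%, 5.05%, 8.55%, 6.43%, 7.32% and 5% of calls in the same order over 10 simulations. The 7-month value (range 5.56% to 10.98%) lies above the 5% aimed at. The simulated counts held no difference between libraries. These shares thus do not cover calls made by a library difference at 3 months or between the 6-month strains.

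The alternatives fixed in advance were a margin rule for hashtags (top tag at least 3 times the second, at least 10 UMIs), leaving out each mouse, RLE factors, DESeq2 1.42.0, no filter on low counts, thinning all mice of a fit to the lowest total, no sex term, all single cells, a stricter filter (1000 genes, 5% mitochondrial), fits of only the groups compared, no library term, a library term for the strains of the QC set, thinning to 1000 UMIs, unthinned shares, a 95th percentile, Apoe added to the DAM index, camera at an estimated correlation and fry. Added after the data were seen were the low-depth cluster, cells below the DAM-high cutoff, the unassigned mouse as APP-NLGF Ctrl, QC libraries 1, 2 and 4 alone, each 7-month library alone, shares of other cells without each mouse, shares at 6 months within library, and the margin rule with the main cutoff. Each other setting of the share set its own cutoff from its own cells: with the margin rule it was 2.99 at 3 months and 3.18 at 6 and 7 months. Cells below the DAM-high cutoff in the fits are those under the cutoff of the unthinned share of UMIs (0.128% at 3 months, 0.178% at 6 and 7 months). Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used for the rest.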

Results

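The series asks what loss of Aph1 in microglia does to their transcriptome in mice with and without the amyloid-forming APP-NLGF alleles, and whether tamoxifen by itself does the same. Microglia-like cells of 38 mice in 10 groups were compared. In parentheses after a gene stand its log2 fold change ± standard error and its adjusted p from edgeR. The labels leave open which Ctrl mice at 3 and 7 months got tamoxifen, so cKO against Ctrl can hold its effect as well.

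Aph1a, which encodes a subunit of gamma-secretase (ENSMUSG00000015750, GRCm38 chromosome 3, 95893969 to 95898288, plus strand, GENCODE M21), was lower in cKO mice at 3 and 7 months. In 3-month C57Bl6 mice it stood at 4.28 ± 2.37 CPM against 31.7 ± 6.88 in 3 cKO and 4 Ctrl mice (-2.81 ± 0.21, adjusted p = 6.26e-13). In 3-month APP-NLGF mice it stood at 2.56 ± 0.863 CPM against 32.6 ± 2.25 (-3.67 ± 0.22, adjusted p = 1.64e-15, 4 mice each), and in 7-month APP-NLGF mice at 2.84 ± 0.473 CPM against 24.9 ± 4.11 (-3.09 ± 0.12, adjusted p = 2.84e-12, 4 mice each). In the 6-month QC set, mice labelled cKO did not differ from Ctrl: 27.7 ± 1.61 CPM against 27.1 ± 5.27 in C57Bl6 (0.11 ± 0.13, adjusted p = 0.871, 4 mice each) and 20.5 ± 5.62 CPM against 25.8 ± 2.96 in APP-NLGF (-0.18 ± 0.14, adjusted p = 0.739, 4 and 3 mice). The fall at 7 months was larger than the change at 6 months (-2.92 ± 0.21, adjusted p = 6.74e-09 for the difference).

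Among the other subunits, Psen2, Ncstn and Psenen moved little. Psen2, a catalytic subunit, Ncstn, the substrate receptor, and Psenen, which is needed for maturation of the complex, passed in no comparison of cKO with Ctrl, and the lowest adjusted p among them was that of Psen2 in 3-month APP-NLGF mice (-0.24 ± 0.090, adjusted p = 0.0619). Aph1b (chromosome 9, 66775202 to 66795490) had too few UMIs to be tested. Aph1c, its close paralog next to it (66814994 to 66834726), was lower at 7 months at 0.669 ± 0.245 CPM against 1.33 ± 0.122 (-1.02 ± 0.29, adjusted p = 0.0109). Whether reads are shared by the paralogs was not tested.

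**Figure D1:**
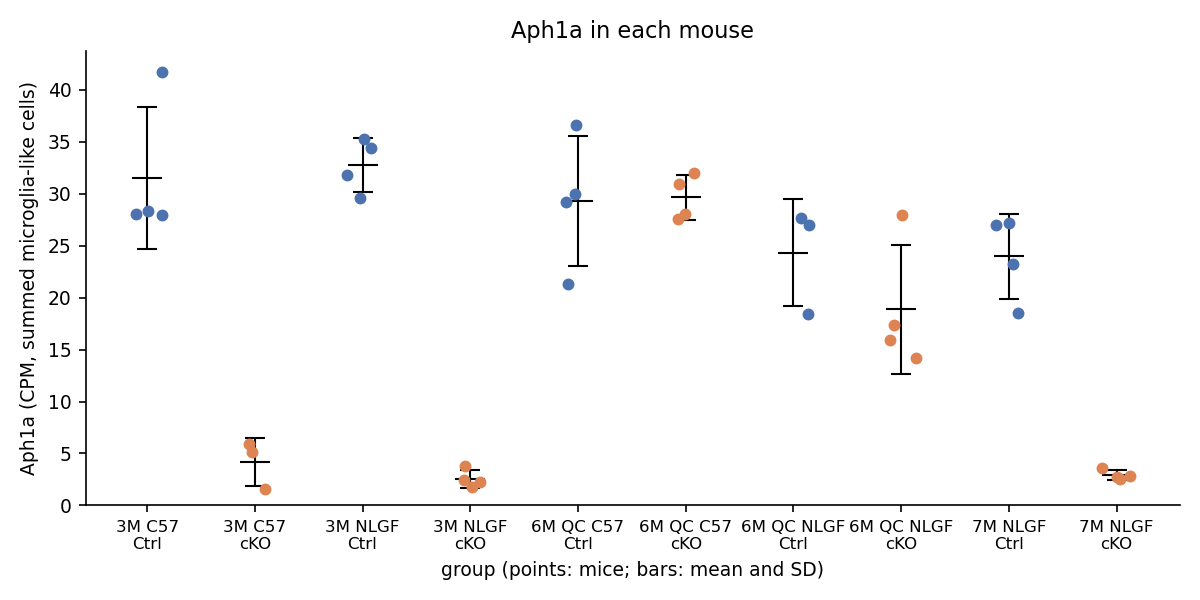
Aph1a in CPM (y axis) in microglia-like cells of each mouse (points) of the 10 groups (x axis), with mean and SD, without TMM factors. The cKO means are 4.19, 2.57 and 2.95 CPM at 3 and 7 months against 31.5, 32.8 and 24 in Ctrl, while mice labelled cKO at 6 months have means of 29.7 and 18.9 CPM.

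Microglia of 3-month C57Bl6 cKO mice (n = 3, Ctrl n = 4) had more transcripts of genes of disease-associated microglia. Apoe, the main lipid carrier of the brain, rose from 606 ± 185 to 1693 ± 337 CPM (1.45 ± 0.22, adjusted p = 0.000995). Lyz2 (lysozyme), the cathepsin Ctsb and Tyrobp, the adaptor of Trem2, rose with it (1.02 ± 0.067, 0.56 ± 0.040 and 0.15 ± 0.038). Of the DAM stage 1 genes 6 of 7 rose (camera adjusted p = 7.13e-07, adjusted p = 0.0808 with an estimated correlation). Of the DAM stage 2 genes 14 of 23 rose and 1 fell (camera adjusted p = 1.01e-11, adjusted p = 0.077 with an estimated correlation, 17 and 1 adjusted over the list alone). Among them were Lgals3, a lectin of phagocytes (2.86 ± 0.67, adjusted p = 0.0167), the inhibitory receptor Lilrb4a (2.15 ± 0.29) and the lipase Lpl (1.28 ± 0.25). The adhesion molecule Cadm1 fell (-0.58 ± 0.14).

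Immediate early genes rose in the same mice, 13 of 19 (camera adjusted p = 3.34e-12, adjusted p = 0.0808 with an estimated correlation, 16 and 0 adjusted over the list alone), with Fos (1.60 ± 0.27, adjusted p = 0.00259) and Klf4 (1.27 ± 0.18) among them. Of the cytokines and chemokines 6 of 17 rose (camera adjusted p = 4.84e-05, adjusted p = 0.0995 with an estimated correlation, 10 and 1 adjusted over the list alone). Among them were Ccl3 (1.23 ± 0.15, adjusted p = 0.000173), Ccl2 (1.14 ± 0.24) and Tnf (1.08 ± 0.22). Oxidative phosphorylation had 11 of 21 genes higher (camera adjusted p = 3.47e-08, adjusted p = 0.0995 with an estimated correlation). In glycolysis Hk2, Pgk1, Eno1 and Ldha rose, 4 of 14 (camera adjusted p = 0.0032, adjusted p = 0.147 with an estimated correlation). Lysosome genes had 13 higher and 5 lower of 34 (camera adjusted p = 0.000399, adjusted p = 0.213 with an estimated correlation), and proliferation 6 of 19 higher (camera adjusted p = 4.84e-05, adjusted p = 0.197 with an estimated correlation).

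Of 8 complement genes C3ar1 (0.62 ± 0.082), C5ar1 (0.57 ± 0.13), C1qa and C1qb were among the higher ones and Itgam was lower (camera adjusted p = 0.024, adjusted p = 0.194 with an estimated correlation). MHC class I had H2-K1, H2-D1, B2m and H2-Q6 higher of 14 (camera adjusted p = 0.00706, adjusted p = 0.292 with an estimated correlation). Interferon response had Ifi207, Ifi27l2a and Cxcl10 higher of 24 (camera adjusted p = 0.000973, adjusted p = 0.325 with an estimated correlation). Lipid efflux had Apoe, Pltp, Abca1 and Abcg1 higher of 11 (camera adjusted p = 0.0343, adjusted p = 0.147 with an estimated correlation), and Pltp turned to -0.48 when all single cells were used.

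TGF-beta signalling keeps microglia in their resting program, and its receptor gene Tgfbr1 fell (-0.42 ± 0.039, adjusted p = 2.87e-12). It fell with the targets Smad7 (-0.18 ± 0.049) and Pmepa1 (-0.36 ± 0.044), 3 of 11 genes of the pathway (camera adjusted p = 0.00187, adjusted p = 0.119 with an estimated correlation). MHC class II had H2-Oa (-0.93 ± 0.098) and H2-DMb1 (-0.31 ± 0.059) lower of 7 (camera adjusted p = 0.00706, adjusted p = 0.194 with an estimated correlation). Hes1, a classical target of Notch, fell (-0.71 ± 0.14, adjusted p = 0.000286). Rbpj, the DNA-binding partner of Notch, rose (0.33 ± 0.061), and the list of 10 genes did not pass (camera adjusted p = 0.974). Of 15 substrates of gamma-secretase App, Trem2, Lrp1 and Cd44 rose and Sorl1 fell (camera adjusted p = 0.0459, adjusted p = 0.137 with an estimated correlation). Homeostatic microglia genes went both ways, 6 higher and 7 lower of 25 (camera adjusted p = 0.207).

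Outside these lists Cdkn1a, the cell cycle inhibitor p21 (2.25 ± 0.31, adjusted p = 0.000559), Mrc1, the mannose receptor of border macrophages (2.06 ± 0.26), Tagln2, an actin-binding protein (1.58 ± 0.098), and the endocytic adaptor Dab2 (1.40 ± 0.12) were higher. Lower were Il7r, the receptor of interleukin 7 (-1.34 ± 0.20), the endothelial marker Pecam1 (-1.17 ± 0.16) and the protease inhibitor Spint1 (-1.14 ± 0.16). Of the other cell types, S100a4 of monocytes (2.71 ± 0.47) and Slc1a3 of astrocytes (0.17 ± 0.055) were higher. The globin genes Hba-a2 (-4.67 ± 0.85), Hbb-bs (-3.93 ± 0.66) and Hba-a1 (-4.89 ± 0.88) were lower, and the last 2 turned to 0.84 and 0.67 when all single cells were used. In all, 1440 of 10915 genes changed (754 higher, 686 lower), 922 with DESeq2. Between the groups 2369 genes (21.7%, 5.71% by chance) did not overlap. Each 3-month group had its own 10x library, so library and group cannot be told apart in any 3-month comparison.

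The cells of 3-month C57Bl6 cKO mice also fell into clusters in other shares. Cluster 0 held 29.4% to 32.8% of the single cells of cKO and 12.97% to 19.8% of Ctrl mice, and cluster 2 held 39.2% to 41.9% against 64.1% to 66.1%. Mitochondrial UMIs were 1.51% to 1.56% against 1.21% to 1.29%, and ribosomal genes held 7.01% to 7.21% against 5.68% to 6.12%. A change of state and a difference between libraries could each give this, and the shares were not tested.

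In 3-month APP-NLGF mice (4 per arm), cKO microglia again had more Apoe, 1623 ± 176 against 686.7 ± 90.2 CPM (1.24 ± 0.20, adjusted p = 0.0014), Lyz2 (1.04 ± 0.062) and Ctsb (0.42 ± 0.037). DAM stage 2 genes split. Spp1 (osteopontin) rose (3.67 ± 1.00, adjusted p = 0.0285), with wide scatter and overlapping mice at 321 ± 346 CPM against 23.4 ± 27.9. Ctsl (0.96 ± 0.046), Cd9 (0.74 ± 0.093), Timp2, Cd63 and Ctsz rose. Lpl (-1.55 ± 0.18, adjusted p = 1.00e-04), Cst7 (-0.99 ± 0.12), Cox6a2 (-1.47 ± 0.25), Cadm1, Ank and Cd52 fell. With 6 of 23 higher and 6 lower, the list did not pass (camera adjusted p = 0.784, median 0.011 and mean -0.044). DAM stage 1 had 3 of 7 higher and Fth1 lower (camera adjusted p = 0.00765, adjusted p = 0.399 with an estimated correlation). In cells below the DAM-high cutoff the change of Lpl was 0.21.

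Hes1 fell further here (-1.87 ± 0.18, adjusted p = 3.31e-11), and the Notch target Nrarp (-1.53 ± 0.42) and the receptor gene Notch4 (-1.34 ± 0.37) were lower. Notch1, Rbpj and Maml2 rose, and the Notch list did not pass (camera adjusted p = 0.98, median 0.12 and mean -0.37). Of the TGF-beta pathway 6 of 11 genes fell, with Tgfbr1 (-0.54 ± 0.036, adjusted p = 9.48e-17) and Smad7 (-0.52 ± 0.045) among them, and Nrros rose (camera adjusted p = 0.00673, adjusted p = 0.263 with an estimated correlation). MHC class I had 5 of 14 genes higher and Tapbp lower (camera adjusted p = 0.00765, adjusted p = 0.526 with an estimated correlation), with H2-Q6 (1.65 ± 0.27) and H2-D1 (0.89 ± 0.10) among them. MHC class II had H2-Oa (-1.46 ± 0.10) and H2-DMb1 lower of 7 (camera adjusted p = 0.00765, adjusted p = 0.396 with an estimated correlation). Complement receptors C5ar1 (0.75 ± 0.11) and C3ar1 rose with C1qa and C1qb (camera adjusted p = 0.0104, adjusted p = 0.396 with an estimated correlation). Of the proliferation genes 7 of 19 rose, Mki67 (1.66 ± 0.51) among them (camera adjusted p = 0.00765, adjusted p = 0.548 with an estimated correlation). Of the cytokines, Il1a (-0.93 ± 0.14), Ccl4 (-0.83 ± 0.23), Ccl3, Cxcl16 and Icam1 fell and Cd83 rose (camera adjusted p = 0.529).

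Outside the lists Cdkn1a (2.79 ± 0.29, adjusted p = 5.95e-05), Mrc1 (2.51 ± 0.27), Tgfbi (1.96 ± 0.13), Tagln2 (1.58 ± 0.092) and Dab2 (1.41 ± 0.12) rose. Gcnt2, a glycosyltransferase (-2.57 ± 0.20, adjusted p = 2.50e-09), Il7r (-1.86 ± 0.21), Spint1 (-1.65 ± 0.17) and Pecam1 (-1.61 ± 0.17) fell. In all, 1928 genes changed (898 higher, 1030 lower), 1253 with DESeq2. Between the groups 1991 genes (18.2%, 2.86% by chance) did not overlap. Genes called in both strains were 317 higher and 344 lower, against 62 and 64.7 for independent lists. Of the markers of other cells Slc1a3 was higher (0.19 ± 0.051), and Mag of oligodendrocytes (-0.44 ± 0.11), Hba-a1 and Hba-a2 were lower.

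In 3-month APP-NLGF mice cluster 0 held 65.6% to 69.2% of the single cells of cKO and 13.5% to 17.7% of Ctrl mice, and cluster 2 held 17.6% to 21.2% against 67.4% to 70.7%. Median UMIs per cell were 3856 to 4030 against 2526 to 2823, mitochondrial UMIs 1.63% to 1.71% against 1.44% to 1.56%, and Malat1 held 2.80% to 3.12% against 3.26% to 3.50% of UMIs. These differences run with the libraries as well.

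The response to the cKO label differed between the strains at 3 months for 489 genes (179 more positive and 310 more negative in APP-NLGF). Of the DAM stage 2 genes 11 of 23 were more negative in APP-NLGF (camera adjusted p = 8.69e-11, adjusted p = 0.0641 with an estimated correlation, 0 and 14 adjusted over the list alone). Among these were Lpl (-2.84 ± 0.31, adjusted p = 0.000299), Lilrb4a (-2.47 ± 0.38), Cox6a2 (-2.17 ± 0.37) and Cst7 (-1.86 ± 0.24). Immediate early genes were more negative too (8 of 19, camera adjusted p = 6.02e-12, adjusted p = 0.0641 with an estimated correlation). So were the cytokines Ccl3, Ccl4 and Cxcl16 (3 of 17, camera adjusted p = 3.52e-06, adjusted p = 0.0641 with an estimated correlation). In glycolysis Hk2, Eno1 and Hif1a were more negative (3 of 14, camera adjusted p = 3.33e-06, adjusted p = 0.0641 with an estimated correlation). Without 3-month C57Bl6 cKO replicate 2 the count was 287 genes, with DESeq2 it was 293, and another split of the mice called 785. Chance could thus not be excluded for this difference.

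At 7 months APP-NLGF cKO mice (4 per arm, both arms in each library) had fewer transcripts of most genes of the DAM lists. Cst7, a cystatin of plaque-associated microglia, fell from 1592 ± 137 to 341 ± 82.3 CPM (-2.25 ± 0.099, adjusted p = 2.85e-05). Cox6a2 (-2.17 ± 0.24), Ank (-1.94 ± 0.086), the integrin Itgax (-1.51 ± 0.047), the lectin Clec7a (-1.37 ± 0.099), Axl (-1.47 ± 0.051) and Igf1 (-1.36 ± 0.15) fell with it. Of 26 DAM stage 2 genes 21 fell and 0 rose (camera adjusted p = 7.04e-15, adjusted p = 0.252 with an estimated correlation, median -1.13). Of DAM stage 1, 6 of 7 genes fell (camera adjusted p = 2.29e-05, adjusted p = 0.252 with an estimated correlation). Apoe stood at 7767 ± 1680 against 13229 ± 686 CPM (-0.79 ± 0.14, adjusted p = 0.0168). Tyrobp (-0.64 ± 0.036, adjusted p = 7.35e-11) and Fth1 (-0.67 ± 0.040) were lower, and the lipid and amyloid receptor Trem2 fell too (-0.48 ± 0.033, adjusted p = 1.20e-09).

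The share of DAM-high cells was 21.5 ± 3.86% in 7-month cKO and 49.8 ± 3.55% in Ctrl mice (-28.3 points, two-sided exact permutation p = 0.0286, and 0.125 when permuted within library and sex, in each case the smallest possible). Cluster 3 held 7.19% to 12.7% of the single cells of cKO and 33.3% to 38.5% of Ctrl mice, and cluster 0 held 62.9% to 69.2% against 41.8% to 44.4%. Changes in the sum of all microglia-like cells can thus come from the mix of cells. In cells below the DAM-high cutoff of the unthinned share, in a comparison added after the data were seen, 1370 genes were called, and the changes of Apoe, Trem2 and Tyrobp were 0.67, 0.10 and 0.059. Of the genes named below, Ch25h (0.40), Ndufa1 (0.096), Pcna (0.022), Hif1a (0.016), Aplp2 (0.011), Inpp5d (-0.062) and Il6 (-0.053) also turned there.

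**Figure D2:**
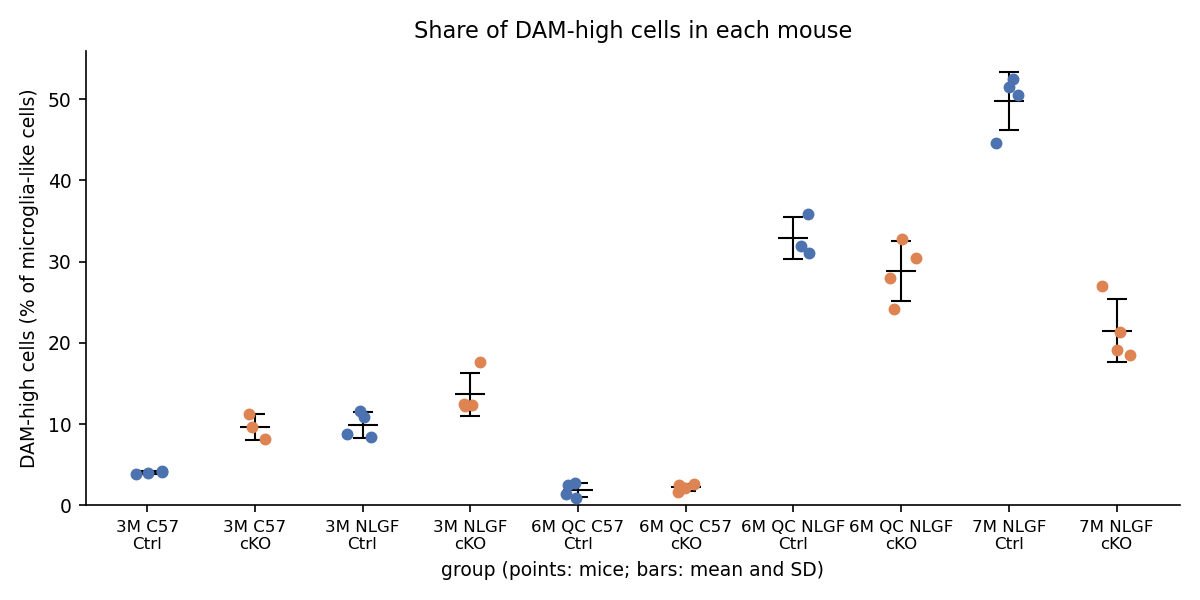
Share of DAM-high cells in percent of microglia-like cells (y axis) in each mouse (points) of the 10 groups (x axis), with mean and SD. At 7 months the means are 21.5% in cKO and 49.8% in Ctrl, at 6 months in APP-NLGF 28.9% in mice labelled cKO and 32.9% in Ctrl, and at 3 months in APP-NLGF 13.7% and 9.92%.

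Metabolic genes fell with the DAM genes at 7 months. Cholesterol synthesis had 16 of 24 genes lower (camera adjusted p = 2.90e-10, adjusted p = 0.129 with an estimated correlation, 0 and 17 adjusted over the list alone). Among them was Sqle, squalene epoxidase (-1.92 ± 0.26, adjusted p = 3.25e-05). Glycolysis had 12 of 15 lower (camera adjusted p = 1.40e-06, adjusted p = 0.252 with an estimated correlation). Of these, Hif1a (-0.89 ± 0.038), the glucose transporter Slc2a1 (-0.93 ± 0.19) and Pgk1 (-0.79 ± 0.11) changed most. Oxidative phosphorylation had 18 of 21 lower (camera adjusted p = 1.52e-10, adjusted p = 0.252 with an estimated correlation), Ndufa1 (-0.73 ± 0.036) among them. Lipid efflux genes split, with Abca1, Abcg1, Mylip, Lpcat3 and Pltp higher and Apoe, Scd2, Srebf1, Plin2 and Soat1 lower of 12 (camera adjusted p = 0.985, median -0.096 and mean 0.023). Ribosomal genes held 10.2 ± 0.31% of UMIs in cKO and 13.5 ± 0.528% in Ctrl mice, and median UMIs per cell were 5564 to 6123 against 6653 to 7099.

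Antigen presentation genes were lower as well. Cd74, the invariant chain, stood at 150.4 ± 134 CPM against 871 ± 385 (-2.85 ± 0.59, adjusted p = 0.0299). With H2-Ab1 (-2.21 ± 0.47), H2-Oa (-1.62 ± 0.076), H2-DMa and H2-DMb1, 5 of 7 genes of MHC class II fell (camera adjusted p = 1.51e-05, adjusted p = 0.252 with an estimated correlation, 0 and 7 adjusted over the list alone). Of MHC class I B2m, Psmb8, Psmb9, H2-Q4 and H2-M3 fell, 5 of 14 (camera adjusted p = 0.00991, adjusted p = 0.609 with an estimated correlation). Of 35 lysosome genes 15 fell and Scarb2 and Tfeb rose (camera adjusted p = 0.000927, adjusted p = 0.252 with an estimated correlation). Cytokines had 7 of 17 lower and Ccl7, Cd83 and Il6 higher (camera adjusted p = 0.0397, adjusted p = 0.609 with an estimated correlation). Ccl3 (-0.96 ± 0.10) and Il1b (-1.14 ± 0.29, adjusted p = 0.0497) were among the lower ones. Interferon response had Rsad2 higher and Ifit2 and Phf11b lower of 25 (camera adjusted p = 0.0397, adjusted p = 0.698 with an estimated correlation).

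Homeostatic genes went the other way at 7 months. Of 25 genes 17 rose and Selplg and Tgfbr1 fell (camera adjusted p = 1.53e-05, adjusted p = 0.252 with an estimated correlation, 18 and 2 adjusted over the list alone). Crybb1 (0.87 ± 0.047), the transcription factor Maf (0.79 ± 0.042), the purine receptor P2ry12 (0.23 ± 0.042) and Tmem119 (0.29 ± 0.046) were among them. Of 4 estrogen receptor genes Esr1, Ncoa2 and Ncoa3 rose (camera adjusted p = 0.0212, adjusted p = 0.252 with an estimated correlation). The Notch list went both ways. Notch1, Notch2, Rbpj, Maml2 and Lfng rose, and Hes1 (-0.91 ± 0.22), Nrarp, Notch4 and Dll1 fell, of 12 (camera adjusted p = 0.985). Gamma-secretase substrates had 8 of 16 higher, Cd44 among them (1.61 ± 0.094), and Aplp2, Axl and Trem2 among the lower ones (camera adjusted p = 0.437).

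The remaining lists did not pass as a whole at 7 months, apart from the subunits, where Aph1a and Aph1c fell of 6 (camera adjusted p = 0.0213, adjusted p = 0.252 with an estimated correlation). TGF-beta pathway had Smad2 and Nrros higher and Tgfb1, Tgfbr1, Tgfbr2, Smad7 and Pmepa1 lower of 11 (camera adjusted p = 0.361). TREM2 signalling had Syk, Inpp5d and Cd33 higher and Trem2, Tyrobp, Plcg2 and Apoe lower of 14 (camera adjusted p = 0.985). Complement had C1qa, C1qb, C1qc, C3ar1 and C5ar1 higher and C3 (-1.90 ± 0.24) and Itgb2 lower of 10 (camera adjusted p = 0.203, median 0.14 and mean -0.010). Immediate early genes had 7 higher and Atf3, Btg2 and Zfp36 lower of 19 (camera adjusted p = 0.132). Proliferation had Cenpf higher and Pcna lower of 19 (camera adjusted p = 0.985).

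Outside the lists, the chemokine receptor Ccr1 (2.63 ± 0.59, adjusted p = 0.0385), vimentin (Vim, 1.73 ± 0.12), lamin A (Lmna, 1.66 ± 0.17), Tagln2 (1.64 ± 0.062) and Tgfbi (1.46 ± 0.064) rose at 7 months. Etl4 (-2.34 ± 0.14), Pacsin1 (-2.24 ± 0.20), Ch25h, which makes 25-hydroxycholesterol (-2.22 ± 0.098), and Il4i1 (-2.10 ± 0.17) fell. Of the markers of other cells, Mrc1 (2.41 ± 0.20) and F13a1 (1.64 ± 0.31) of border macrophages, Vcan and Ccr2 of monocytes and Slc1a3 of astrocytes were higher. Ms4a4c of monocytes, Ighm of B cells, Pecam1 and Flt1 of endothelium and Folr1 of choroid plexus were lower. Of 15 microglia markers 11 were higher and Trem2 lower, and Kdm5d was higher among the sex-linked genes. No tested marker of neutrophils, dendritic cells, oligodendrocytes, neurons or erythroid cells was called, and those of T or NK cells and mural cells had too few UMIs to be tested. Border macrophage-like cells were 3.24 ± 0.815% of cKO and 2 ± 0.894% of Ctrl cells (exact permutation p = 0.114).

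In all, 3524 of 12484 genes changed at 7 months (1662 higher, 1862 lower), and 2696 (21.6%, 2.86% by chance) did not overlap between the arms. With library left out as a term 2053 genes were called, and within library 1 and library 2 alone, with 1 mouse per arm and sex, 2215 and 2045. False calls made up 8.55% of calls in simulations of this design, above the 5% aimed at, and no list call held with an estimated correlation.

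**Figure D3:**
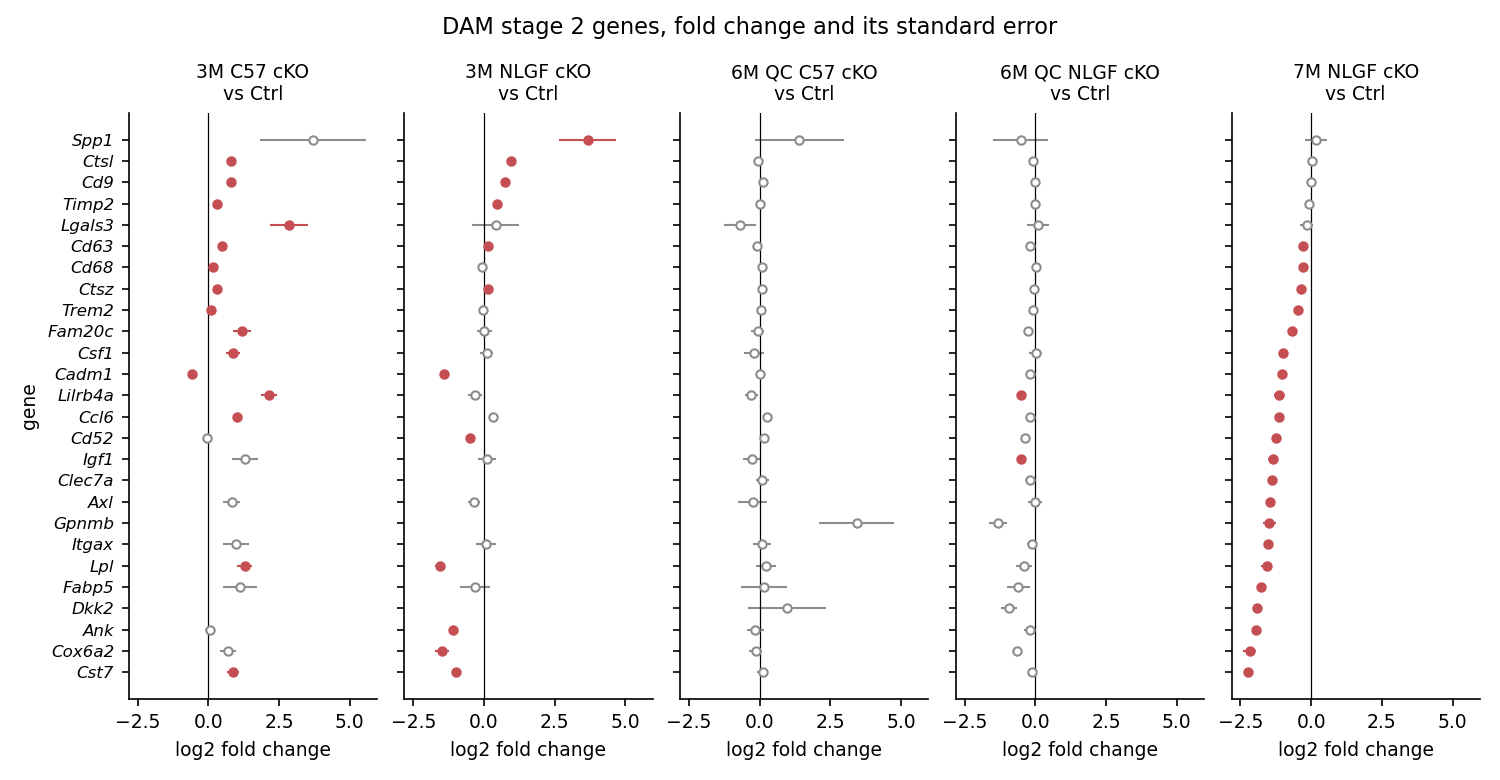
Log2 fold change (x axis) and its standard error (bars) of each DAM stage 2 gene (y axis) in the 5 comparisons of cKO with Ctrl, filled in red at adjusted p under 0.05 and open in grey otherwise. Of the genes tested, 14 rise and 1 falls in 3-month C57Bl6, 6 rise and 6 fall in 3-month APP-NLGF, 0 and 2 in 6-month APP-NLGF, and 0 rise and 21 fall at 7 months.

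In the 6-month QC set few genes differed between mice labelled cKO and Ctrl. Its libraries differed: cluster 4 held 47.9% to 58.0% of the single cells of the 6 mice of libraries 3 and 5, and 1.03% to 12.3% in the 10 mice of libraries 1, 2 and 4. In C57Bl6 mice (4 per arm) labelled cKO some genes of proliferation were higher. Rrm2, a subunit of ribonucleotide reductase, stood at 3.42 ± 1.03 CPM against 0.590 ± 0.299 (2.40 ± 0.36, adjusted p = 0.00241). Esco2 (2.10 ± 0.29, adjusted p = 0.000834), Pclaf (1.11 ± 0.21), Pbk (1.13 ± 0.23) and Stmn1 (0.42 ± 0.076) were higher too. Rrm2, Pclaf and Stmn1 belong to the proliferation list, 3 of 19 (camera adjusted p = 3.90e-08, adjusted p = 0.534 with an estimated correlation, 5 and 0 adjusted over the list alone). The chaperones Hspa8 (-0.26 ± 0.048) and Stip1 (-0.38 ± 0.071) and the actin-binding Ablim1 (-0.66 ± 0.13) were lower. No gene of the other 20 lists was called by edgeR. In all, 10 of 11820 genes were called (7 higher, 3 lower), 957 at unadjusted p under 0.05 and 2 with DESeq2. Only 137 genes (1.16%, 2.86% by chance) did not overlap.

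This count for 6-month C57Bl6 mice moved when mice or libraries were left out. It was 3 without cKO replicate 1, cKO replicate 3, Ctrl replicate 2 or Ctrl replicate 3, and 6 without cKO replicate 2. It was 49 and 48 without cKO replicate 4 and Ctrl replicate 4. These were the only mice fitted from the fifth QC library, so leaving out either takes that library out of the comparison. In QC libraries 1, 2 and 4 alone it was 46. With library left out as a term it was 0 (957 at unadjusted p under 0.05 with the term).

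Of the 6-month APP-NLGF mice (4 labelled cKO, 3 Ctrl), Ctrl replicate 3 sat in a library with no APP-NLGF mouse labelled cKO. With library as a term, the fold changes thus rest on Ctrl replicates 1 and 2, both female. In mice labelled cKO Adrb1, the beta-1 adrenergic receptor, was higher (0.87 ± 0.10, adjusted p = 2.16e-05) with Crybb1 (0.37 ± 0.058, adjusted p = 0.00178), 1 of 25 homeostatic genes (camera adjusted p = 4.19e-05, adjusted p = 0.563 with an estimated correlation, 3 and 0 adjusted over the list alone). Egln3, a prolyl hydroxylase of HIF (-0.88 ± 0.14, adjusted p = 0.00134), Ero1l (-0.56 ± 0.11), Slc2a1 (-0.46 ± 0.097) and Bnip3 (-0.41 ± 0.080) were lower. Slc2a1, Bnip3, Pkm and Pgk1, 4 of 14 glycolysis genes, fell (camera adjusted p = 4.56e-09, adjusted p = 0.563 with an estimated correlation, 0 and 11 adjusted over the list alone). The DAM stage 2 genes Igf1 (-0.52 ± 0.090, adjusted p = 0.0136) and Lilrb4a (-0.50 ± 0.11, adjusted p = 0.0275) were lower, 2 of 26 (camera adjusted p = 5.61e-05, adjusted p = 0.563 with an estimated correlation, 0 and 7 adjusted over the list alone). In oxidative phosphorylation 0 genes were called by edgeR, although the list was lower as a whole (camera adjusted p = 5.89e-05, adjusted p = 0.563 with an estimated correlation). Slc1a3, a marker of astrocytes, was higher (0.31 ± 0.059).

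In all, 42 genes were called in 6-month APP-NLGF mice (19 higher, 23 lower), 1162 at unadjusted p under 0.05, and 319 genes (2.7%, 5.71% by chance) did not overlap. Of the 23 lower genes 17 were also lower at 7 months (3.5 for independent lists, 0 opposite), and of the 19 higher 6 were also higher (2.6 for independent lists, 1 opposite). Of the genes called at 7 months and tested at 6 months, 72.87% of those lower and 60.41% of those higher had the same sign in 6-month APP-NLGF mice (45.41% and 44.72% in C57Bl6 mice). Tamoxifen or a chance difference between these 6-month mice could each give this, so whether some of the 7-month change goes with tamoxifen stays open. The count was 5 and 11 without Ctrl replicates 1 and 2, 22 without cKO replicate 3, 9 with DESeq2, 16 in QC libraries 1, 2 and 4 alone and 1 with library left out as a term. The share of DAM-high cells was 28.9 ± 3.69% in mice labelled cKO and 32.9 ± 2.56% in Ctrl (exact permutation p = 0.229, the smallest possible 0.0571). In C57Bl6 mice it was 2.23 ± 0.42% and 1.9 ± 0.901% (p = 0.571, exact permutation). The tamoxifen effect differed between the strains for 11 genes, although chance could not be excluded. Crybb1 (0.55 ± 0.071, adjusted p = 0.000125), Adrb1, Lrrc25, Ddit4 and 1 predicted gene were more positive in APP-NLGF. Rrm2 (-2.22 ± 0.45), Ccne2, St8sia6, Adssl1, Padi2 and Txn1 were more negative. This last count was 23 without APP-NLGF cKO replicate 1, 3 without APP-NLGF Ctrl replicate 1, and 5 without C57Bl6 cKO replicate 2, APP-NLGF cKO replicate 2 or APP-NLGF Ctrl replicate 2. It was 6 without APP-NLGF cKO replicate 3, C57Bl6 cKO replicate 3 or C57Bl6 Ctrl replicate 3, and 7 without APP-NLGF Ctrl replicate 3.

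The change at 7 months differed from that of the tamoxifen set for 1161 genes (388 more positive, 773 more negative). More negative at 7 months were 17 of 26 DAM stage 2 genes (camera adjusted p = 8.08e-12, adjusted p = 0.0761 with an estimated correlation), with Cst7 (-2.24 ± 0.20, adjusted p = 2.07e-05), Axl (-1.51 ± 0.22) and Itgax (-1.48 ± 0.17) among them. So were 12 of 23 cholesterol synthesis genes (camera adjusted p = 1.41e-10, adjusted p = 0.0297 with an estimated correlation), with Sqle (-1.50 ± 0.43), and 9 of 14 glycolysis genes (camera adjusted p = 5.25e-06, adjusted p = 0.223 with an estimated correlation). Oxidative phosphorylation had 13 of 21 genes more negative (camera adjusted p = 1.40e-10, adjusted p = 0.0761 with an estimated correlation). More positive were Tagln2 (1.66 ± 0.092, adjusted p = 1.14e-11), Lmna (1.92 ± 0.35), Mrc1 (2.18 ± 0.43) and Maf (0.65 ± 0.082). The count was 533 and 690 without 6-month APP-NLGF Ctrl replicates 1 and 2, 671 with all mice thinned to the lowest total and 149 with library left out as a term.

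The change at 7 months differed from that in APP-NLGF mice at 3 months for 1288 genes (469 more positive, 819 more negative). All 7 DAM stage 1 genes were more negative at 7 months (camera adjusted p = 4.97e-13, adjusted p = 0.00728 with an estimated correlation), with Apoe (-2.05 ± 0.25, adjusted p = 2.97e-05) and Lyz2 (-1.23 ± 0.11). So were 15 of 25 DAM stage 2 genes (camera adjusted p = 4.24e-13, adjusted p = 0.0134 with an estimated correlation), with Cst7 (-1.28 ± 0.20) and Ctsl (-0.97 ± 0.080). Cholesterol synthesis (13 of 23, camera adjusted p = 7.32e-09, adjusted p = 0.00728 with an estimated correlation) and oxidative phosphorylation (17 of 21, camera adjusted p = 8.61e-14, adjusted p = 0.0191 with an estimated correlation) were more negative too. Homeostatic genes were more positive (10 of 25, 1 more negative, camera adjusted p = 6.54e-08, adjusted p = 0.0134 with an estimated correlation). The count was 856 after thinning. Called in both APP-NLGF comparisons were 352 genes higher and 419 lower (131 and 154 for independent lists).

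Between the strains, 3-month APP-NLGF Ctrl microglia (4 mice per strain) had more transcripts of DAM stage 2 genes than C57Bl6 Ctrl microglia. Cst7 stood at 61.4 ± 13.6 against 8.7 ± 1.76 CPM (2.89 ± 0.15, adjusted p = 5.77e-14), and Lpl (2.68 ± 0.20, adjusted p = 4.40e-06), Axl (1.98 ± 0.25) and Ccl6 (1.05 ± 0.13) were higher, 15 of 23 genes (camera adjusted p = 1.72e-10, adjusted p = 0.0501 with an estimated correlation). Glycolysis was higher in 13 of 14 genes (camera adjusted p = 1.51e-08, adjusted p = 0.0459 with an estimated correlation), with Hif1a (0.56 ± 0.062) and Pkm (0.44 ± 0.063). Immediate early genes were higher (11 of 19, camera adjusted p = 4.96e-08, adjusted p = 0.141 with an estimated correlation). Of the cytokines Ccl3, Ccl4, Cxcl16, Nfkbiz and Icam1 were higher (5 of 17, camera adjusted p = 0.000586, adjusted p = 0.141 with an estimated correlation). Of the lysosome genes 14 of 34 were higher and 3 lower (camera adjusted p = 0.000262, adjusted p = 0.308 with an estimated correlation). Of the homeostatic genes 16 of 25 were lower (camera adjusted p = 8.67e-05, adjusted p = 0.118 with an estimated correlation), P2ry13 (-0.44 ± 0.043) among them.

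Apoe did not differ between the strains at 3 months (0.18 ± 0.21, adjusted p = 0.633). Lars2, a mitochondrial leucyl-tRNA synthetase, and AY036118, a transcript of the ribosomal DNA, were lower in APP-NLGF (-2.78 ± 0.055 and -2.16 ± 0.064), as were the histones Hist1h1e (-1.64 ± 0.19) and Hist1h4d (-1.45 ± 0.068). The share of DAM-high cells was 9.92 ± 1.59% in APP-NLGF and 4.04 ± 0.143% in C57Bl6 Ctrl mice (exact permutation p = 0.0286, the smallest possible). In all, 1939 genes differed (1017 higher, 922 lower), 1146 with DESeq2. Of the genes tested, 1982 (18.2%, 2.86% by chance) did not overlap.

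Quality also differed between the 3-month strains, each in its own libraries. Median UMIs per cell were 2526 to 2823 in APP-NLGF and 3333 to 3544 in C57Bl6 Ctrl mice, mitochondrial UMIs 1.44% to 1.56% against 1.21% to 1.29%, and Malat1 held 3.26% to 3.50% against 2.40% to 2.62% of UMIs. Ribosomal genes held 6.315% to 6.53% against 5.676% to 6.115%. Cluster 1, with Lars2, Hist1h1e and Hist1h4d among its leading genes, held 0.248% to 0.606% against 2.755% to 6.263% of single cells. Cluster 3 held 2.076% to 3.053% against 0.093% to 0.344%. Of the markers of other cells, Cd79b of B cells (-0.42 ± 0.097) and the globin Hbb-bs (-2.14 ± 0.50) were lower in APP-NLGF and Slc1a3 (0.19 ± 0.052) higher.

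Among 3-month cKO mice (4 APP-NLGF, 3 C57Bl6) 1750 genes differed between the strains (862 higher, 888 lower), 1039 with DESeq2 and 1035 without C57Bl6 cKO replicate 2. Of the genes tested, 2755 (25.2%, 5.71% by chance) did not overlap. Cst7 (1.03 ± 0.17, adjusted p = 6.10e-05), Axl (0.80 ± 0.25) and Ctsl (0.23 ± 0.050) were higher in APP-NLGF and Lilrb4a and Cadm1 lower, 5 of 23 DAM stage 2 genes (camera adjusted p = 0.915). Oxidative phosphorylation had 6 of 21 genes lower (camera adjusted p = 0.00184, adjusted p = 0.365 with an estimated correlation), and Hes1 (-1.41 ± 0.20), Lars2 (-2.45 ± 0.056) and AY036118 (-2.57 ± 0.065) were lower. Of the markers of other cells, S100a4 of monocytes was lower and Slc1a3 higher. Cluster 0 held 65.6% to 69.2% of the single cells of APP-NLGF and 29.4% to 32.8% of C57Bl6 cKO mice. The low-depth cluster held 6.02% to 7.65% against 16.5% to 17.6%.

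At 6 months the strains stood far apart. APP-NLGF Ctrl mice (n = 3) had 8264 ± 3570 CPM of Apoe against 684 ± 89.8 in C57Bl6 Ctrl mice (n = 4, 3.55 ± 0.34, adjusted p = 8.11e-06). Cst7 stood at 1242 ± 249 CPM against 14.9 ± 5.07 (6.41 ± 0.33, adjusted p = 1.23e-08). Higher were 24 of 26 DAM stage 2 genes (camera adjusted p = 2.28e-45, adjusted p = 0.00246 with an estimated correlation), Itgax (4.26 ± 0.20), Clec7a (4.11 ± 0.30) and Lpl (4.41 ± 0.29) among them, and all 7 of DAM stage 1 (camera adjusted p = 1.45e-10, adjusted p = 0.0484 with an estimated correlation). So were 18 of 35 lysosome genes (camera adjusted p = 1.94e-12, adjusted p = 0.0484 with an estimated correlation), 10 of 14 of glycolysis (camera adjusted p = 1.89e-10, adjusted p = 0.0484 with an estimated correlation) and 8 of 19 of proliferation (camera adjusted p = 1.18e-09, adjusted p = 0.0484 with an estimated correlation). The same held for 6 of 23 of cholesterol synthesis (camera adjusted p = 5.46e-06, adjusted p = 0.0164 with an estimated correlation) and 5 of 7 of MHC class II (camera adjusted p = 5.46e-06, adjusted p = 0.171 with an estimated correlation). Lower were P2ry13, Slc2a5, Crybb1 (-1.10 ± 0.20), Maf (-0.67 ± 0.18) and Gpr165 (-1.44 ± 0.30), 5 of 25 homeostatic genes (camera adjusted p = 1.10e-05, adjusted p = 0.0406 with an estimated correlation).

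In this comparison 924 of 11820 genes differed (641 higher, 283 lower), 1529 with library as a term and 577 with all single cells. The count was 502 and 564 without C57Bl6 Ctrl replicate 1 and APP-NLGF Ctrl replicate 1. Of the genes tested, 2177 (18.4%, 5.71% by chance) did not overlap. With all single cells Il1b, H2-Aa and H2-Ab1 turned to -0.91, -0.23 and -0.23. The share of DAM-high cells was 32.9 ± 2.56% against 1.9 ± 0.901% (exact permutation p = 0.0571, the smallest possible). In cells below the cutoff 6 genes were called. Cluster 3 held 19.98% to 24.8% of the single cells of APP-NLGF and 0.351% to 0.888% of C57Bl6 Ctrl mice, and ribosomal genes 10.2% to 14.1% against 6.42% to 8.54% of UMIs. Over the 11756 genes tested in both, differences by strain at 6 months and changes in 7-month cKO mice tended to be opposite (Pearson r = -0.589 across genes, which are not independent replicates). Of the genes called higher in 7-month cKO mice, 146 were called lower and 11 higher in 6-month APP-NLGF Ctrl mice. Of those called lower, 517 were called higher there and 12 lower.

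At 3 months the share of DAM-high cells was 9.7 ± 1.59% in C57Bl6 cKO mice and 4.04 ± 0.143% in Ctrl (exact permutation p = 0.0571, the smallest possible). It was 13.7 ± 2.65% in APP-NLGF cKO mice and 9.92 ± 1.59% in Ctrl (exact permutation p = 0.0286). The latter difference of 3.76 points was 0.5 with unthinned shares and 2.11 after thinning to 1000 UMIs, neither past the threshold, and 1.96 with Apoe and 5.91 with a 95th percentile (exact permutation p = 0.0286 in each case). With the margin rule for hashtags it was 0.53 where the cutoff moved from 2 to 2.99, and 3.61 (exact permutation p = 0.0286) with the main cutoff, added after the data were seen. The difference in C57Bl6 mice, 5.66 points, was 2.48 with the margin rule and its cutoff of 2.99, 5.33 with that rule and the main cutoff, 3.28 after thinning to 1000 UMIs, 3.56 with unthinned shares, 3.57 with Apoe and 11 with a 95th percentile. That between the strains in Ctrl, 5.88 points, was 0.993 with Apoe, 3.88 after thinning to 1000 UMIs and 8.84 with a 95th percentile. Cells outside the microglia-like clusters were 19.6 ± 0.776% in 3-month C57Bl6 cKO mice against 12.8 ± 3.74% in Ctrl (exact permutation p = 0.0571). They were 9.64% in both arms of 3-month APP-NLGF mice, and 15.7 ± 2.29% against 8.63 ± 1.02% at 7 months (exact permutation p = 0.0286, and 0.125 within library and sex). The sort can set such shares, which was not tested, and most of the gain was in the low-depth cluster, 11.8 ± 2.68% against 6.32 ± 0.547% at 7 months (exact permutation p = 0.0286). At 6 months the shares were 25.9 ± 8.26% against 21.7 ± 9.84% in C57Bl6 and 11.7 ± 3.38% against 13.2 ± 5.8% in APP-NLGF mice (exact permutation p = 0.514 and 0.571). Within library, in a comparison added after the data were seen, the differences were 4.21 points in C57Bl6 (p = 0.0833, the smallest possible) and 1.84 in APP-NLGF mice (p = 0.556), by exact permutation of the arms. Leaving out 1 mouse gave 0.862 to 8.87 points in C57Bl6 mice across libraries.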

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

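Of the tests below, 7 were chosen after the result was seen: the comparison with the tamoxifen set, the sign at 7 months of genes called in both strains at 3 months, the signs at 6 months of genes higher and of genes lower in APP-NLGF mice at 3 months, and the directions of genes called again at 7 months (C57Bl6 and APP-NLGF) and at 6 months. Cells below the DAM-high cutoff were an alternative added after the data were seen.

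The loss of DAM stage 2 genes in 7-month cKO mice was weighed first. Tamoxifen as the whole cause is argued against, since 17 of 26 genes were lower in the difference from the 6-month set. Unequal totals of UMIs per mouse are argued against, since 21 of 26 were lower after all mice were thinned to the same total. Random thinning keeps each gene's share of a total on average. It cannot decide on depth per cell, which stays open. Fewer DAM-high cells with the other cells alike stays open: in cells below the DAM-high cutoff the median change of 13 DAM stage 2 genes outside the index was 0.18 (quartiles 0.103 and 0.375), against -0.418 in all microglia-like cells, which met what was set in advance for this cause. That test decides nothing, since the cells were chosen by the DAM score and the genes went both ways (Timp2, Ctsl, Cd63, Cd9, Fam20c and Cd68 higher, Cadm1 lower at -0.72). A part of the change may go with tamoxifen (17 of the 23 genes lower in 6-month APP-NLGF mice were also lower at 7 months). Chance could not be excluded for the 6-month genes, so this stays open. Slower growth of plaques, fewer plaques and a change inside microglia were not tested.

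For the genes changed between cKO and Ctrl mice at 3 months, a library difference as the whole cause is argued against for the 986 genes of APP-NLGF mice called again at 7 months, where both arms share a library, since 78.19% had the same direction (66.48% of all genes called higher and 69.78% of those called lower had the same sign). Genes can move together and are not independent replicates, which limits this test. For the 754 genes of C57Bl6 mice called again at 7 months the share was 49.6% (47.35% and 48.91%), which a library difference was set to give. Of the genes higher in C57Bl6, 205 were shared and 255 opposite at 7 months (110.2 and 113.1 for independent lists). Of those lower, 169 were shared and 125 opposite (102.8 and 100.1). This test cannot decide, since a response that differs between strains or ages could give opposite directions too. A library difference and a difference between strains stay open. The term for library within the 7-month set called 2581 of 12484 genes, more than the 1440 of C57Bl6 mice, which a library difference was set to give. Totals per mouse were 11975953 to 21911799 UMIs in the 7-month fit and 2509809 to 5925474 in the 3-month fit. They were not matched for this test, so it cannot tell how many genes a library difference would give at 3 months. Of 660 genes called the same way in both strains, 65% had the same sign at 7 months, between what a library difference and what a cKO effect were set to give. The difference in the labelled genotype stays open as well, and Aph1a fell in both comparisons.

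For the genes that differed between APP-NLGF and C57Bl6 Ctrl mice at 3 months, 49.65% of 1007 genes higher and 53.47% of 922 genes lower at 3 months kept their sign at 6 months. These shares are what a library difference could give, and a difference between the ages stays open. For the 251 genes called at both ages a library difference as the whole cause is argued against, since 84.06% had the same direction. Called higher at both ages were 164 genes (49.3 for independent lists) and lower 47 (23.5), with Pearson r = 0.276 across genes, which are not independent replicates. The 6-month strains also sat mostly in separate libraries.

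The count of genes was compared with counts from other splits of the same mice into groups of the same sizes. The real split gave the most genes for 3-month C57Bl6 cKO against Ctrl (1440 genes, highest other 543, 1 of 35 splits as large). The same held for 3-month APP-NLGF cKO against Ctrl (1928 and 2, 1 of 35) and for the strains at 3 months in Ctrl (1939 and 2, 1 of 35) and in cKO (1750 and 499, 1 of 35). At 3 months only the real split followed the libraries, so this test cannot tell an effect of the group from a library difference. The real split was also the largest for the strains at 6 months (924 and 230, 1 of 35), which sat mostly in separate libraries. Chance is argued against for 7 months (3524 and 197, 1 of 35, the smallest share possible). At 7 months the highest other split followed the libraries and was fitted without the library term; the real split gave 2053 without it. Among the 33 splits with all terms the highest other was 2. For the difference of 7 and 3 months (1288 genes, highest other 1, 1 of 30) the other splits mixed mice of the 2 ages, which sat in separate libraries. The real split kept the ages apart, so this test decides nothing about the effect. For the difference of 7 and 6 months (1161 and 747, 1 of 30) no other split kept the library terms of the real fit, which limits this test. Chance could not be excluded for the 6-month C57Bl6 mice (10 genes, highest other 3482, 5 of 35 splits as large), the 6-month APP-NLGF mice (42 and 1834, 3 of 35), the difference between strains at 3 months (489 and 785, 2 of 30) and at 6 months (11 and 30, 3 of 30). The splits that gave 3482 and 1834 genes followed the libraries and were fitted without the library term, where the real splits gave 0 and 1, so they point to a structure of the samples by library. With all terms, 4 of 34 splits were as large in C57Bl6 mice (highest other 19) and 1 of 33 in APP-NLGF mice (highest other 7). The splits did not keep the library blocks.

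Among 112 groups of mice and measures, 8 had one mouse far from the others, where chance gives about 1 in 20 groups. The share of DAM-high cells was 17.7% in 3-month APP-NLGF cKO replicate 3, with the others at 12.3% to 12.5%. The low-depth cluster held 7.81% of cells of 7-month APP-NLGF cKO replicate 3 (others 12.8% to 13.6%), and border macrophage-like cells were 5.16% of 6-month APP-NLGF replicate 1 labelled cKO (others 3.73% to 3.94%). Microglia-like cells numbered 1440 in 3-month APP-NLGF Ctrl replicate 2 (others 1042 to 1090) and 1744 in 6-month C57Bl6 Ctrl replicate 4 (others 1031 to 1130). Mitochondrial UMIs were 1.63% in 3-month APP-NLGF cKO replicate 1 (others 1.7% to 1.71%). Aph1a was at 41.7 CPM in 3-month C57Bl6 Ctrl replicate 2 (others 27.9 to 28.3), and Psen2 at 41.1 CPM in 3-month APP-NLGF cKO replicate 4 (others 33.1 to 33.6).

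Effects differed between groups, by a test of the difference, for 489 genes between strains at 3 months, 11 between strains at 6 months, 1161 between 7 and 6 months and 1288 between 7 and 3 months. Chance could not be excluded for the 489 and 11 genes by the splits above, nor library differences for the 489 and 1288 genes. In the male Ctrl mouse of the fifth QC library, without a strain in the labels and with a tag named NLGF in the matrix, 396 of 1336 microglia-like cells were DAM-high (29.64%, Wilson 95% confidence interval 27.3% to 32.1%, counting error only), against 1.9 ± 0.901% in 6-month C57Bl6 Ctrl mice. The share was 32.9 ± 2.56% in 6-month APP-NLGF Ctrl mice and 28.9 ± 3.69% in those labelled cKO.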

How the results depend on the processing

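Among the alternatives, 8 kinds were added after the data were seen: the low-depth cluster, cells below the DAM-high cutoff, the unassigned mouse as APP-NLGF Ctrl, QC libraries 1, 2 and 4 alone, each 7-month library alone, shares of other cells without each mouse, shares at 6 months within library, and the margin rule with the main cutoff. Of the counts, list calls and shares under alternatives, 295 kept their direction and stayed past or short of the threshold (counts within 1.5 times), 73 moved, 35 became weaker and 10 reversed. Of 8079 values of 420 pairs of a gene and a comparison (241 genes), 7282 were the same, 740 weaker, 4 stronger and 53 reversed. Of the smallest simulated changes 26% or fewer were found in the 6-month comparisons. Where no cause is named, the cause was not tested.

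With DESeq2 the counts were 922, 1253, 1146 and 1039 (3-month C57Bl6 cKO, APP-NLGF cKO, strains in Ctrl, strains in cKO) and 293 (3-month difference). At 7 months the count was 2053 with no library term, 1370 in cells below the DAM-high cutoff, and 2215 and 2045 in library 1 and 2 alone, where fewer mice were fitted. For the 6-month C57Bl6 mice it was 2 with DESeq2, 149 with no filter, 4 with the margin rule, 4 with all single cells, 6 after thinning, 3 with no sex term, 0 with no library term, 5 below the cutoff and 46 in QC libraries 1, 2 and 4. For the 6-month APP-NLGF mice it was 9 with DESeq2, 187 with no filter, 4 with all single cells, 6 after thinning, 27 with no sex term, 1 with no library term, 13 below the cutoff and 16 in QC libraries 1, 2 and 4, and with the unassigned mouse as APP-NLGF Ctrl it was 39. For the 6-month difference it was 3 with DESeq2, 90 with no filter, 4 with the margin rule, 3 with all single cells, 2 after thinning, 2 with no sex term and 0 with no library term. For the 6-month strains it was 577 with all single cells, 1529 with library added and 6 below the cutoff, for 7 minus 6 months 671 after thinning and 149 with no library term, and for 7 minus 3 months 856 after thinning. The cause was not tested.

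With 1 mouse left out, counts ran from 1035 to 1616 (strains in 3-month cKO) and from 287 to 510 (3-month difference), lowest without 3-month C57Bl6 cKO replicate 2 in each case. They ran from 3 to 49 (6-month C57Bl6), 5 to 44 (6-month APP-NLGF), 3 to 23 (6-month difference), 502 to 906 (6-month strains) and 533 to 1212 (7 minus 6 months). With an estimated correlation the lists called by camera were 0 for 3-month C57Bl6 and APP-NLGF cKO, 7 months and both 6-month comparisons, 1 for the 3-month strains and 8 for the 6-month strains, and fry called 0 in both 6-month comparisons of labelled cKO with Ctrl.

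The difference in DAM-high cells in 3-month APP-NLGF mice was 0.53 points with the margin rule, which also moved the cutoff from 2 to 2.99 (3.61 with the main cutoff), 2.11 after thinning to 1000 UMIs and 0.5 with unthinned shares. Leaving out 1 mouse gave 2.44 to 4.33 points there, 5.32 to 6.4 for the 3-month strains and -30.1 to -27.3 at 7 months, all short of the threshold because the smallest p of 3 against 4 mice is 0.0571, as for other cells at 7 months (6.3 to 8.09 points). In 6-month C57Bl6 mice it reversed to -0.377 with the margin rule, which also moved the cutoff from 3 to 3.18 (0.234 with the main cutoff), -0.125 unthinned, -0.318 with Apoe and -0.014 without 6-month C57Bl6 Ctrl replicate 1 (range to 0.619). The share of other cells ran from -0.241 to 0.144 points in 3-month APP-NLGF mice with 1 mouse left out. It reversed without Ctrl replicate 4 and cKO replicates 1, 3 and 4 (-0.241, -0.032, -0.013 and -0.048). In 6-month APP-NLGF mice it ran from -3.39 to 1.84 and reversed without Ctrl replicate 3 and within library (1.84).

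In cells below the DAM-high cutoff, log2 fold changes at 7 months reversed for Apoe (0.67), Ch25h (0.40), Glb1 (0.12), Trem2 (0.10), Baiap2l2 (0.10), Ndufa1 (0.096), Cox4i1 (0.087), Tyrobp (0.059), Ncstn (0.040), Pcna (0.022), Hif1a (0.016), Psenen (0.015), Aplp2 (0.011), Psen2 (0.0033), Gpr165 (-0.084), Inpp5d (-0.062) and Il6 (-0.053). They did so elsewhere for H2-Aa (-0.28) and Gla (-0.22) between the 6-month strains, Lpl (0.21) in 3-month APP-NLGF cKO mice, Tyrobp (-0.016) between the 3-month strains and Psen2 (0.081) in 6-month APP-NLGF mice. Leaving out the cells that score high removes transcripts of the DAM index by construction. For genes outside the index the cause of the reversal was not tested. With all single cells, reversals were Cxcl2 (-1.45), Cd44 (-0.94), Il1b (-0.91), H2-Aa (-0.23) and H2-Ab1 (-0.23) between the 6-month strains, Hbb-bs (0.84), Hba-a1 (0.67) and Pltp (-0.48) in 3-month C57Bl6 cKO mice and Aph1c (-0.16) in 6-month C57Bl6 mice. With the low-depth cluster they were Hbb-bs (0.85) and Hba-a1 (0.74) in 3-month C57Bl6 cKO mice.

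The remaining reversals were of subunits near 0. In 3-month C57Bl6 mice Ncstn was -0.011 without cKO replicate 4 (range to 0.079). In 6-month C57Bl6 mice Ncstn was -0.0025 after thinning, Psen2 0.0046 with no library term, 0.072 in QC libraries 1, 2 and 4, and 0.012, 0.058, 0.048, 0.017 and 0.057 without Ctrl replicates 3 and 4 and cKO replicates 1, 3 and 4 (range from -0.10). There Aph1c was -0.11 and -0.12 without Ctrl replicate 1 and cKO replicate 1 (range to 0.70). In 6-month APP-NLGF mice Psenen was 0.00080 with the margin rule, 0.024 after thinning, 0.098 with no library term and 0.015 without cKO replicate 3 (range from -0.025). Psen2 was 0.059 with no library term, 0.094 in QC libraries 1, 2 and 4, and 0.080 and 0.054 without Ctrl replicate 2 and cKO replicate 3 (range from -0.13). Aph1c was -0.24 without Ctrl replicate 2 (range to 1.05). The cause was not tested.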

Other observations

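A set of 287 genes was called the same way in cKO mice of both strains at 3 months and at 7 months (142 higher, 145 lower), and the set was chosen after the values were seen. Ahnak, a scaffold protein of the cell cortex, was nearly absent from Ctrl microglia, so no fold is given: it stood at 3.93 ± 1.14 CPM against 0 ± 0 in 3-month C57Bl6, 4.34 ± 1.93 CPM against 0 ± 0 in 3-month APP-NLGF and 6.82 ± 1.91 CPM against 0.399 ± 0.146 in 7-month APP-NLGF mice. The folate receptor Folr2 was at 3.46, 4.77 and 2.98 on the log2 scale in the same order, from group means of at most 3.54 CPM in Ctrl mice. The hyaluronan receptor Cd44, itself cut by gamma-secretase, was at 2.9, 3.73 and 1.61, and the intermediate filament gene Vim at 2.5, 2.95 and 1.73. Lamin A (Lmna) was at 2.52, 2.19 and 1.66, and the integrin Itga4 at 1.8, 2.33 and 1.91. Lower in all 3 were Procr, the protein C receptor (-1.16, -1.58 and -1.6), and Spint1 (-1.14, -1.65 and -1.56). So were the matrix metalloprotease Mmp14 (-0.99, -1.31 and -1.61) and Upk1b (-0.96, -1.5 and -1.27).

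In mice labelled cKO of the 6-month set none of these was called, and Ahnak was not tested there. Folr2 was at -0.06, Cd44 at -0.11, Vim at -0.22, Lmna at -0.06, Itga4 at 0.29, Procr at -0.04 and Spint1 at 0.02 in APP-NLGF mice. In C57Bl6 mice they were at 1.24, 0.33, -0.6, -0.34, -0.8, 0.22 and 0.03 in the same order. Of the 287 genes, 2 were called in 6-month APP-NLGF mice and 0 in 6-month C57Bl6 mice by edgeR (2 in all with DESeq2, 957 of all genes at unadjusted p under 0.05). Folr2 and Mrc1 are also genes of border macrophages. The share of border macrophage-like cells was 2.15 ± 0.459% in 3-month C57Bl6 cKO mice against 2.5 ± 0.951% in Ctrl (exact permutation p = 0.629) and 2.23 ± 0.498% against 2.02 ± 0.496% in 3-month APP-NLGF mice (exact permutation p = 0.571). At 7 months it was 3.24 ± 0.815% against 2 ± 0.894% (exact permutation p = 0.114).

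The male Ctrl mouse of the fifth QC library, with no strain in the labels and a tag named NLGF in the matrix, had 8.59 CPM of Aph1a in 1348 microglia-like cells. The other 6-month mice had 14.2 to 36.6 CPM and the cKO mice of 3 and 7 months 1.54 to 5.9 CPM, and its genotype was not checked further. The 3-month C57Bl6 cKO mouse left out for few cells had 12 microglia-like cells among 21 single cells.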
